A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

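Total RNA from 20 cultures of Saccharomyces cerevisiae was measured on 10 two-channel arrays of 60-mer probes. The cultures were wild type or carried 1 of 4 temperature-conditional alleles of TAF5 (taf5-17, taf5-45, taf5-408 or taf5-10.4), which encodes a subunit of the transcription factor TFIID and of the co-activator SAGA. Per the labels, cells were grown at 23 °C to mid-log phase, diluted with warm or 23 °C medium, and held for 2 hours at 37 °C or at 23 °C. The whole experiment was run on 2 occasions, each giving 10 cultures, so that the replicate number is the run and the same number pairs samples across groups.

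Each of the 10 groups (5 genotypes at 2 temperatures) held 2 samples. The 23 °C and the 37 °C culture of 1 genotype and run shared 1 array. Every 23 °C sample was labelled with Cy5 and every 37 °C sample with Cy3, so temperature and dye cannot be told apart within a genotype. A mutant and the wild type at 1 temperature carried the same dye, and so did both sides of the interaction with temperature.

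The deposited values are intensity values on a linear scale, made by the authors with RMA, whose version is not given in the sources used here, nor is the set of arrays that was normalized together. They ranged from 27.5 to 51113, and no detection calls come with them. Each of 5735 genes had 1 value in each of 2 blocks of probe sets, 11470 values per sample. Of these genes, 5681 had 11 probe pairs per block and 54 had fewer, down to 1. The labels describe 5777 genes with 8 probe pairs each and 3-fold redundancy, which differs from the values analysed here. The series' table and the single tables of each sample were equal in every cell (largest difference 0). A gene's value was the mean of its log2 intensities over the 2 blocks. Locus tags were paired with gene symbols from a RefSeq table, which held 5729 of the 5735 tags, and 532 genes kept their systematic names. Gene positions are those in the arrays' own annotation, whose genome build is not given in the sources used here. The number of arrays limits the precision.

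Differences were tested with limma 3.58.1 in R 4.3.3 on all 20 samples, with 10 group means and the shared array as a random block (correlation 0.344). The residual degrees of freedom were 10. Contrasts compared each allele with wild type at 37 °C and at 23 °C, the interaction of each allele with temperature, 37 °C with 23 °C within each genotype, and the alleles with each other at 37 °C, 23 contrasts in all. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p under 0.05 were called. The standard error (SE) of a difference comes from the same model, and standard deviations (SD) are over n = 2 samples.

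A total of 33 gene lists were tested with camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry, each adjusted over the lists of 1 contrast. A list's count of called genes is given over all genes tested and, where stated, adjusted over the list alone. Of 29 translation factors 26 were found by name, of 41 Gcn4 targets 40 and of 23 hexose genes 22. Some entries of a list named the same gene and were merged. The 26 Mediator entries were all found and gave 25 genes. The 16 mitochondrially encoded entries gave 7 genes, with only the entries VAR1 and Q0140 not found. The lists, contrasts, alternatives and the choice of named genes were fixed before the data were examined. The named genes were TAF5, then for each allele at 37 °C the 5 highest and the 5 lowest differences among called genes with the same sign in both same-numbered pairs, and 3 per side for the other mutant contrasts. The wild type shift took 10 per side, genes called in all 4 alleles up to 10 per side, and each list its 2 highest and 2 lowest members by mean difference over the alleles at 37 °C. Probes cannot separate near-identical paralogs, and the sequence changes of the alleles are not visible to them.

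Alternatives were quantile normalization within each dye, cyclic loess over all samples, centring each sample on the mitochondrial ribosomal protein genes, omission of the dimmest 25% of genes, the median of a gene's 2 values, no array block, the replicate number as a block (residual degrees of freedom 9), limma-trend, a fold minimum of 1.5, only the groups of a contrast, only arrays of 1 scan number, and each sample left out in turn. Added after the data were seen were a replicate block within each temperature, scan number as a block, each block of probe sets alone, and omission of the taf5-17 replicate 1 array. The value with a replicate block is given where it ends or makes a printed call or moves a printed count by over 1.5 times.

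The procedure was tested on a single simulated data set in which 100 genes changed 2-fold and another 100 changed 4-fold. At 4-fold it called 69 of 100 in a mutant contrast at 37 °C and 52 of 100 in an interaction, at 2-fold 15 and 2, with 4 and 5 unchanged genes called. A simulated contrast without change gave 0 calls with limma. The simulated arrays varied independently, without the difference between runs that the measured groups share. Values were read with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.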

Results

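RNA abundance of 5735 genes was measured in wild type yeast and in 4 temperature-conditional taf5 mutants at a permissive temperature of 23 °C and a non-permissive 37 °C, with 2 samples in each of the 10 groups. The median intensity of a sample lay between 258 (taf5-17 at 37 °C, replicate 1) and 314 (wild type at 37 °C, replicate 1). The first principal component held 55.8% of the variance and set the 37 °C samples of taf5-17, taf5-45 and taf5-10.4 apart from the rest. It also separated the runs: 23 °C samples lay at -17.6 to -1.3 in replicate 1 and at -54.9 to -49.8 in replicate 2. The second, with 19.8%, placed replicate 1 above replicate 2 in each group: the difference between replicates correlated across genes between groups at a median r of 0.579 over 45 pairs of groups. Spearman correlations between replicates of a group ran from 0.860 to 0.957 across genes, which are not independent replicates.

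**Figure D1:**
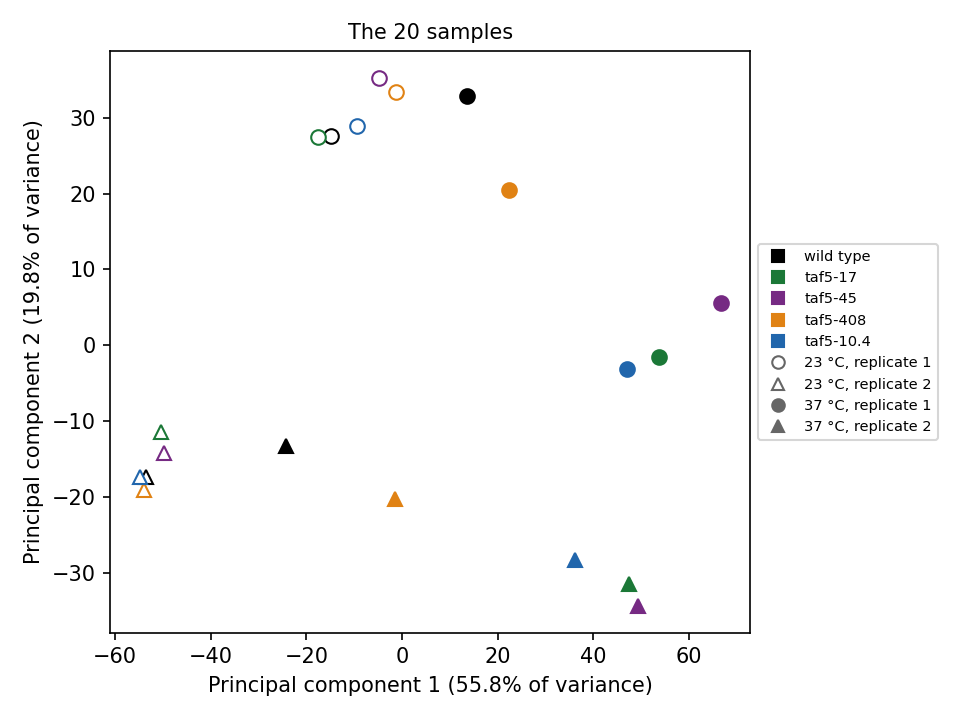
Each of the 20 samples on the first 2 principal components of the log2 gene values (axes in component units, with the percent of variance); colours give the genotype, open symbols 23 °C, filled symbols 37 °C, circles replicate 1 and triangles replicate 2. The 37 °C samples of taf5-17, taf5-45 and taf5-10.4 lie at 36.1 to 66.7 on the first component, and those of wild type and taf5-408 at -24.3 to 22.4.

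The comparison of each mutant with wild type at 37 °C asks which genes differ when the mutant cells are at the non-permissive temperature. In it, rose and fell mean higher and lower than in wild type at 37 °C, not a change with the shift. In taf5-17, taf5-45 and taf5-10.4 cytosolic ribosomal protein genes fell, while taf5-408 gave few calls. The largest rise among the genes called in each allele was that of YHR007C-A, an open reading frame without a standard name, by 7.07 ± 0.35 on the log2 scale (SE, n = 2 per group) in taf5-17, 6.86 in taf5-45, 6.34 in taf5-10.4 and 3.50 in taf5-408. Of the genes called, 395 rose and 652 fell in taf5-17, 296 rose and 561 fell in taf5-45, 169 rose and 315 fell in taf5-10.4, and 4 rose and 1 fell in taf5-408.

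Among the other genes with the largest rises, YCL048W-A rose by 5.56 ± 1.28 in taf5-17 (adjusted p = 0.010), 5.11 in taf5-45 and 4.73 in taf5-10.4. YOR072W-B rose by 4.98 in taf5-17 and 4.07 in taf5-10.4, and YOL013W-A by 4.68 in taf5-17. IRC15, a microtubule-associated protein gene whose position overlaps CTF19, rose by 4.42 ± 0.49 in taf5-17. DAL80, a repressor of nitrogen catabolism genes, rose by 4.90 ± 0.50 in taf5-45 and 4.08 in taf5-10.4, and HXT5, a hexose transporter gene, by 4.44 ± 0.57 in taf5-45. The largest fall in taf5-17 was that of ELP2, an Elongator subunit gene, at -2.94 ± 0.53 (adjusted p = 0.0025). The acid phosphatase gene PHO3 had the largest fall in taf5-45 (-3.70 ± 0.67) and in taf5-10.4 (-2.85). The nicotinic acid transporter gene TNA1 (-2.82 ± 0.73, adjusted p = 0.032), CIR2 (-2.58 ± 0.25) and SPO12 (-2.50 ± 0.50), a regulator of mitotic exit, followed in taf5-10.4. The rest of the 5 lowest in each of these 3 alleles were ribosomal protein genes.

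The totals were 1047 genes in taf5-17, 857 in taf5-45, 484 in taf5-10.4 and 5 in taf5-408, with 1843, 1609, 1179 and 332 at an unadjusted p under 0.05. With a replicate block they were 2017, 1767, 1122 and 16, all calls without the block among them. With only the groups of the contrast in the model, limma called 0 in each allele, with 973, 1458, 1175 and 225 at an unadjusted p under 0.05. The share of calls that fell was 62.3%, 65.5% and 65.1% in taf5-17, taf5-45 and taf5-10.4, against 50.7%, 51.6% and 54.6% after cyclic loess and 32.1%, 46.5% and 71.7% after centring on mitochondrial ribosomal protein genes. That centring moved the median difference of all genes from -0.10 to 0.255 in taf5-17, from -0.09 to 0.06 in taf5-45, from -0.02 to -0.60 in taf5-408 and from -0.08 to -0.20 in taf5-10.4. Single samples also moved the totals by over 1.5 times. For taf5-17 it was 688 without wild type replicate 1 at 37 °C and 580 without replicate 2. For taf5-45 it was 443 without wild type replicate 2, 566 without its own replicate 1 and 464 without its replicate 2. For taf5-10.4 the same 3 omissions gave 254, 258 and 246. For taf5-408 it was 1 without wild type replicate 1, 3 without its own replicate 1 and 1 without its replicate 2. Wild type and taf5-10.4 arrays carry scan number 2 and the others 1 or 4, so scan number and allele cannot be told apart for taf5-17, taf5-45 and taf5-408. Of these, the 23 °C channels of the same arrays gave 0 calls with limma (15, 3 and 33 at an unadjusted p under 0.05). That cannot show whether scan number matters at 37 °C. The test at 23 °C was conservative, and those channels carry the other dye.

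Of the 132 cytosolic ribosomal protein genes, which encode the ribosome's protein components, 120 fell in taf5-17, 125 in taf5-45 and 123 in taf5-10.4 (125, 128 and 127 adjusted over the list alone). Their median differences were -1.97, -2.17 and -1.77. In taf5-408 the median was -0.34, and limma called 0 of them (22 lower at an unadjusted p under 0.05, 0 adjusted over the list alone). The mean of the list was 13.67 ± 0.09 (SD, n = 2) in wild type at 37 °C, 11.85 ± 0.08 in taf5-17, 11.54 ± 0.23 in taf5-45, 11.99 ± 0.10 in taf5-10.4 and 13.32 ± 0.08 in taf5-408, while the 5 genotypes lay between 14.09 and 14.20 at 23 °C. RPS3 was among the lowest, at -2.74 in taf5-17, -3.18 in taf5-45 and -2.54 in taf5-10.4, as was RPL43B at -2.86, -2.95 and -2.43. At the other end RPS14B measured 0.61, -0.15, 0.49 and 0.49 in taf5-17, taf5-45, taf5-408 and taf5-10.4, and RPL15B -0.15, -0.38, 0.09 and -0.26, none of them called. Camera gave adjusted p = 1.12e-61, 8.34e-82 and 1.91e-87 in the 3 alleles, and the calls held with an estimated correlation (adjusted p = 0.0234, 0.00783 and 0.00598). In taf5-408 it was 2.69e-21, and adjusted p = 0.296 with an estimated correlation. The medians kept their sign in each of the 3 other scalings, at -1.67, -1.83, -0.29 and -1.66 after cyclic loess in taf5-17, taf5-45, taf5-408 and taf5-10.4. Relative to the median of all genes, which centring of whole samples leaves as it is, they were -1.87, -2.08, -0.32 and -1.69.

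**Figure D2:**
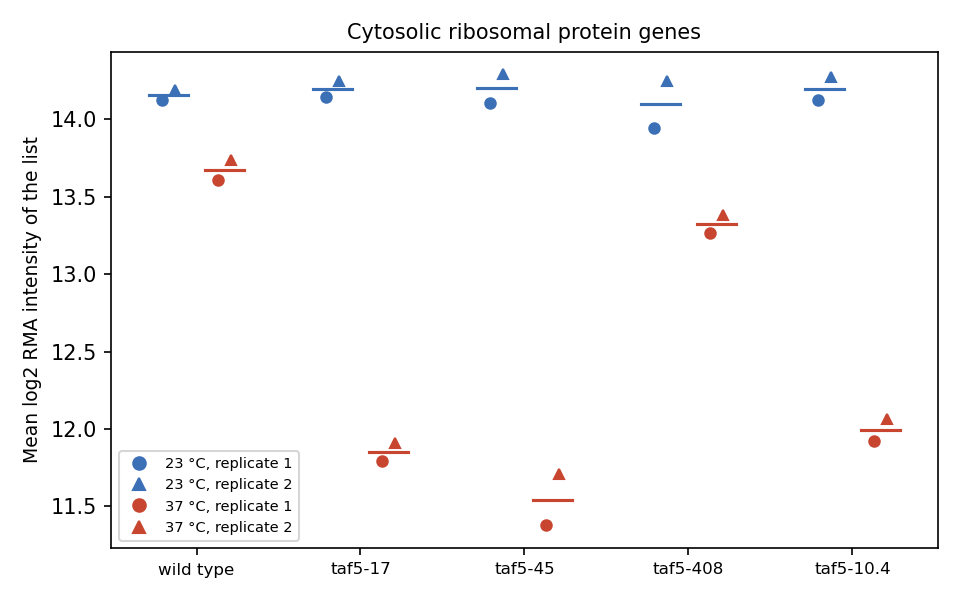
Mean log2 RMA intensity of the 132 cytosolic ribosomal protein genes in each sample, by genotype; blue is 23 °C, red 37 °C, circles replicate 1, triangles replicate 2 and lines group means. At 37 °C taf5-17, taf5-45 and taf5-10.4 have group means of 11.85, 11.54 and 11.99, against 13.67 in wild type and 13.32 in taf5-408.

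Camera called ribosome biogenesis genes lower in the same 3 alleles, translation factors in all 4 and RNA polymerase I and III subunits in taf5-17 and taf5-45, the weakest call at adjusted p = 0.0401. No call held with an estimated correlation (smallest adjusted p = 0.356 with an estimated correlation). Of 90 ribosome biogenesis genes 20 fell in taf5-17, 15 in taf5-45 and 6 in taf5-10.4 (22, 20 and 6 adjusted over the list alone), at medians of -1.11, -1.12 and -0.62, against -0.09 in taf5-408. SDA1 fell in the 3 alleles (-2.24, -2.36 and -2.07), as did UTP10 (-2.25, -2.35 and -1.94), while UTP30 at 1.16, 1.45 and 1.17 was not called, except in taf5-45 with a replicate block (adjusted p = 0.0392). Of 26 translation factor genes 13, 11 and 3 fell (17, 18 and 11 adjusted over the list alone), among them TIF4631 at -2.28, -1.88 and -1.34, and the list medians were -1.16, -1.09 and -0.64, against -0.21 in taf5-408. HYP2, which encodes eIF5A, rose in taf5-17 by 0.75. Among 19 subunits of RNA polymerases I and III, 5 fell in taf5-17 and 6 in taf5-45 (6 and 7 adjusted over the list alone), with RPA135 at -2.12 and -2.57 and medians of -0.94 and -1.23. In taf5-10.4 the polymerase median was -0.59, with 0 genes called (adjusted p = 0.0616 by camera, 0.0360 with a replicate block, and adjusted p = 0.749 with an estimated correlation). With a replicate block 44, 46 and 14 ribosome biogenesis genes fell and 1 rose in taf5-45. The same block gave 17, 20 and 10 translation factor genes lower, and 9, 10 and 6 polymerase genes. The ribosome biogenesis median was -0.65 in taf5-17 without its replicate 1 and -0.28 in taf5-10.4 without wild type replicate 2. That of the polymerase subunits was -0.60, -1.66 and -0.61 in taf5-17 without its replicate 1 and wild type replicates 1 and 2, and -0.52 in taf5-45 without wild type replicate 2. The taf5-408 median of translation factors was -0.37 without its replicate 2.

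Oxidative phosphorylation and tricarboxylic acid genes had medians above 0 in each allele. Of 37 oxidative phosphorylation genes 5 rose and 2 fell in taf5-17, 21 rose and 1 fell in taf5-45, 9 rose in taf5-10.4 and 1 rose in taf5-408 (5 and 2, 29 and 2, 28, and 3 adjusted over the list alone). The replicate block gave 16 higher and 2 lower in taf5-17, 31 and 2 in taf5-45, 26 and 0 in taf5-10.4, and 2 and 0 in taf5-408. Their medians were 0.73, 1.39, 1.28 and 0.72, each above 0 in every scaling. The succinate dehydrogenase gene SDH2 rose by 2.25 in taf5-45 and 2.31 in taf5-10.4, while the ATP synthase genes ATP16 and ATP5 fell in taf5-17 (-1.12 and -1.07). Of 18 genes of the tricarboxylic acid and glyoxylate cycles 7 rose in taf5-17, 9 in taf5-45 and 7 in taf5-10.4 (7, 9 and 10 adjusted over the list alone), with the isocitrate dehydrogenase genes IDH2 at 2.41, 2.49 and 2.74 and IDH1 at 2.36, 2.27 and 2.58. Camera called both lists in all 4 alleles (weakest adjusted p = 8.18e-04), but not with an estimated correlation, where the smallest was adjusted p = 0.286 with an estimated correlation. Without wild type replicate 2 the tricarboxylic acid medians were 0.54, 0.84 and 0.90 in taf5-17, taf5-45 and taf5-10.4, and without taf5-17 replicate 2 the oxidative phosphorylation median in taf5-17 was 0.33. Of 25 ergosterol synthesis genes 7, 5 and 5 rose in taf5-17, taf5-45 and taf5-10.4 (9, 7 and 8 adjusted over the list alone, and 13, 14 and 9 with a replicate block, which also called 1 lower in each of the first 2), among them MVD1 at 1.74 in taf5-17 and 1.52 in taf5-10.4 (smallest adjusted p = 0.362 with an estimated correlation). The ergosterol medians were 0.75, 1.02 and 0.68, and 0.33, 0.38 and 0.24 without wild type replicate 1, 1.15 in taf5-17 without its replicate 1 and 1.04 in taf5-10.4 without wild type replicate 2. The 7 mitochondrially encoded genes were called by camera in taf5-45 and taf5-10.4 and not in taf5-17 (adjusted p = 0.165) or taf5-408 (adjusted p = 0.205). In taf5-10.4 their median was 1.11, with COX3 up by 1.84 there and by 2.11 in taf5-45 (adjusted p = 0.529 and 0.671 with an estimated correlation), and was 0.63 and 1.76 without taf5-10.4 replicates 1 and 2. The 19 genes of glycolysis and fermentation had medians of 0.35, 0.07, 0.33 and 0.41 in taf5-17, taf5-45, taf5-408 and taf5-10.4, with 4, 2, 0 and 3 called higher. Camera did not call the list in taf5-45 (adjusted p = 0.0980). The taf5-408 medians were 0.20 for this list without taf5-408 replicate 1, and 1.05 and 0.20 for tricarboxylic acid genes without wild type replicates 1 and 2. PDC5, a pyruvate decarboxylase gene, rose by 1.88 in taf5-17 (smallest adjusted p for the list = 0.590 with an estimated correlation).

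Stress and iron lists had higher medians in the same alleles. The 37 general stress genes under Msn2 and Msn4 had medians of 1.54, 1.70 and 1.45 in taf5-17, taf5-45 and taf5-10.4, with 3, 3 and 2 genes called (2, 3 and 2 adjusted over the list alone, and 11, 12 and 4 with a replicate block), SIP18 in taf5-45 by 3.85 ± 1.06. CTT1, the cytosolic catalase gene, measured 3.53, 4.08 and 2.83 and was not called without a replicate block, which called it in the first 2 of these. The 27 Hsf1 chaperone genes had medians of 0.83, 1.22 and 0.94, with SSA3 up by 2.14, 2.64 and 2.57. Of them 2, 2 and 1 were called (0, 2 and 1 adjusted over the list alone, and 5, 7 and 4 with a replicate block). In the iron regulon 7 of 22 genes rose in taf5-17, 2 in taf5-45 and 3 in taf5-10.4 (9, 3 and 7 adjusted over the list alone, and 14, 7 and 11 with a replicate block), FIT2 by 3.97 in taf5-17, while ATX1, a copper chaperone gene, fell in each (-1.07, -1.60 and -1.97). The iron medians were 1.40, 0.99 and 1.35. Camera called these 3 lists higher in all 4 alleles (weakest adjusted p = 0.0457), but no call held with an estimated correlation (smallest adjusted p = 0.514 with an estimated correlation). The runs differed in the 37 stress genes by a median of -0.47 at 37 °C, run 2 minus run 1, with 2 higher and 16 lower, and of -3.16 at 23 °C. Single samples moved these medians: without wild type replicate 2 the stress median was 0.85 in taf5-17 and 0.40 in taf5-10.4. The Hsf1 median was 0.20, 0.49 and 0.31 in taf5-17, taf5-45 and taf5-10.4 without wild type replicate 1, 1.42, 1.98 and 1.78 without wild type replicate 2, 1.45 and 0.09 in taf5-17 without its replicates 1 and 2, and 0.71 in taf5-45 without its replicate 2. The iron median was 0.88, 0.44 and 0.87 without wild type replicate 1, 1.67 and 0.16 in taf5-45 without its replicates 1 and 2, and 2.08 and 0.61 in taf5-10.4 without its own.

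Amino acid and phosphate genes were mixed, while 0 methionine and sulfur genes were called lower. Of 40 Gcn4 targets 2 rose and 1 fell in taf5-17, 3 rose and 3 fell in taf5-45 and 1 rose in taf5-10.4, with SER3 at 2.16, 3.02 and 2.29 and ASN2 at -1.48 and -1.94 in the first 2. The replicate block gave 7 higher and 4 lower in taf5-17, 12 and 4 in taf5-45, and 8 and 3 in taf5-10.4. Of 22 methionine and sulfur genes 3 rose in taf5-17 and 3 in taf5-45, MET30 by 1.95 in taf5-45, at medians of 0.83 and 0.68 (8 and 7 with a replicate block, and 2 in taf5-10.4). Among 16 phosphate genes under Pho4, SPL2 rose by 2.40, 1.79 and 1.91 in taf5-17, taf5-45 and taf5-10.4, while PHO3, which phosphate does not repress, fell in all 3 (-2.74 in taf5-17). The list medians were 0.34, 0.52 and 0.43 for Gcn4 targets and 0.70, 0.39 and 0.50 for phosphate genes. With the shift itself SPL2 fell in wild type, and the phosphate median was -0.98 in wild type, -0.85 in taf5-17 and -0.59 in taf5-45. Camera called the 3 lists in these alleles except phosphate in taf5-45 and, with a replicate block, phosphate in taf5-17 (adjusted p = 0.0517). No call held with an estimated correlation (smallest adjusted p = 0.514 with an estimated correlation). Without their own replicate 2 the methionine medians were 0.35 in taf5-45 and 0.29 in taf5-10.4, where it was 0.45 with all samples and 0.27 without wild type replicate 2. The Gcn4 medians were 0.20 and 0.58 in taf5-17 without its replicates 1 and 2, and 0.68 and 0.06 in taf5-10.4 without its own, and the phosphate median in taf5-10.4 was 0.24 without wild type replicate 1. The median of 22 hexose transport and glucose repression genes was -0.06, -0.15, -0.32 and -0.13 in taf5-17, taf5-45, taf5-408 and taf5-10.4, not called by camera, although HXT5 and MIG2 rose in taf5-17, taf5-45 and taf5-10.4 (MIG2 by 2.22, 1.84 and 2.04).

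Cell cycle, mating and proteasome genes followed the alleles unevenly. Of 22 G2/M genes under Mcm1, Fkh2 and Ndd1, 4 fell in taf5-17, 4 in taf5-45 and 3 in taf5-10.4 (4, 6 and 10 adjusted over the list alone, and 14 in each with a replicate block), SPO12 at -2.28, -2.61 and -2.50. Their medians were -1.05, -0.86, -0.49 and -1.03 in taf5-17, taf5-45, taf5-408 and taf5-10.4, called by camera in each (smallest adjusted p = 0.529 with an estimated correlation). In taf5-17, taf5-45 and taf5-10.4 they were -1.81, -1.49 and -1.60 without wild type replicate 1, -0.53, -0.36 and -0.58 without wild type replicate 2, and -1.47 in taf5-45 without its replicate 2. Medians of 41 G1/S genes were -0.08, -0.17, 0.27 and 0.05. AGA1, a mating agglutinin gene of the pheromone response, rose by 3.43, 3.22 and 3.09 in taf5-17, taf5-45 and taf5-10.4, and the a-factor gene MFA1 by 2.90, 3.11 and 2.59. With the shift itself MFA1 fell in wild type. Of the 7 a-specific genes, 0 were called higher with the shift in wild type, taf5-17 or taf5-45, and 3, 1 and 2 were called lower. Of 23 pheromone response genes 5 rose and 1 fell in taf5-17 and 2 rose in taf5-45, at medians of 0.47 and 0.20 (adjusted p = 0.362 and 0.486 with an estimated correlation), the latter 0.32 without taf5-45 replicate 1. Adjusted over the list alone 6 rose and 1 fell in taf5-17 and 1 rose in taf5-45. Numbers with a replicate block were 8 higher and 1 lower in taf5-17 and 5 and 1 in taf5-45. The 7 a-specific genes had medians of 0.92, 0.43, -0.07 and -0.16, called by camera in the first 2 but in taf5-45 not with a replicate block (adjusted p = 0.0544). Neither call held with an estimated correlation (adjusted p = 0.362 and 0.486). The median of taf5-17 was 0.24 without wild type replicate 1. The 5 alpha-specific genes had medians of 0.44, 0.08, -0.17 and 0.08. Of 36 proteasome genes 14 fell in taf5-17 (21 adjusted over the list alone, 25 with a replicate block) at a median of -0.88 (adjusted p = 0.362 with an estimated correlation), PUP3 at -1.42. That median was -0.62 without taf5-17 replicate 1 and -1.41 without replicate 2. The proteasome medians were -0.35 in taf5-45, with 1 gene higher and 5 lower, and -0.20 in taf5-10.4, with 1 lower (1 higher and 1 lower with a replicate block). Adjusted over the list alone 1 was higher and 6 lower in taf5-45, and 0 were called in taf5-10.4. RPN4, the transcriptional activator of the proteasome genes, rose by 1.92 in taf5-45. Of 19 early meiosis genes 4 rose in taf5-17 (11 adjusted over the list alone, 10 with a replicate block), REC104 by 1.03 and SMK1 by 1.17, at a median of 0.57 (adjusted p = 0.362 with an estimated correlation), which cyclic loess took to 0.09 (adjusted p = 0.428) and omission of taf5-17 replicate 1 to 0.34. The taf5-17 replicate 1 sample at 37 °C had the largest SD between its 2 blocks of probe sets, 0.425 against 0.216 to 0.335 in the other samples, and lay higher in dim genes than replicate 2.

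Of 5 lists of the transcription machinery camera called TFIID subunits in taf5-408 (adjusted p = 0.0168, and adjusted p = 0.923 with an estimated correlation) and RNA polymerase II subunits in taf5-17. The medians in taf5-17, taf5-45, taf5-408 and taf5-10.4 were -0.13, 0.12, 0.20 and -0.08 for 15 TFIID subunits, -0.33, -0.27, -0.03 and -0.19 for 19 SAGA subunits, -0.38, 0.03, 0.04 and -0.08 for 18 general factors of RNA polymerase II, and -0.23, -0.08, 0.07 and -0.08 for 25 Mediator subunits. The TFIID median in taf5-408 was 0.11 without wild type replicate 1, 0.37 without taf5-408 replicate 1 and 0.00 without its replicate 2. TRA1, a SAGA subunit gene, fell in taf5-17 (-0.86) and taf5-45 (-1.02). In taf5-17 TAF14 fell (-1.16) and TAF7 rose (1.12). Of the Mediator genes 1 rose and 3 fell in taf5-17, 1 rose and 1 fell in taf5-45 and 1 fell in taf5-10.4 (3 and 3, 3 and 3, and 0 and 3 with a replicate block). The riser was ROX3 in taf5-17 (2.05) and taf5-45 (2.29). SRB7 (-1.41) fell in taf5-17, GAL11 in taf5-17 (-0.96) and taf5-10.4 (-0.96), and MED4, named after its values were seen, in taf5-17 (-1.07) and taf5-45 (-0.85). For 12 RNA polymerase II subunits the medians were -0.79, -0.73, 0.07 and -0.44, called in taf5-17 (adjusted p = 0.0381, and adjusted p = 0.609 with an estimated correlation) and with a replicate block in taf5-45 too (adjusted p = 0.0352, and adjusted p = 0.559 with an estimated correlation), with RPB10 at -1.59. In taf5-17 that median was -0.44 and -1.27 without its replicates 1 and 2 and -1.20 without wild type replicate 1. The 18 SAGA-dependent test genes had medians of 0.70, 0.35, -0.06 and 0.25, with BDF2 up by 3.03, 3.54 and 2.91 in taf5-17, taf5-45 and taf5-10.4 (smallest adjusted p for the list = 0.362 with an estimated correlation). Camera called the list in taf5-17 and taf5-10.4, the latter not with a replicate block (adjusted p = 0.0713). Their median was 0.32 and 1.25 in taf5-17 without its replicates 1 and 2, and in taf5-10.4 0.38 and 0.45 without wild type replicates 1 and 2 and 0.54 without its replicate 2. Core histone genes had medians of 0.31, 0.53, 0.46 and 0.48, and HHT2 rose by 0.81, 0.86 and 0.81 in the same 3 alleles, while HTZ1, a variant histone gene, fell in taf5-45 (-0.87). Cell wall integrity genes under Rlm1 had medians of 0.56, 0.27, 0.30 and 0.45 (smallest adjusted p = 0.520 with an estimated correlation). Of these 22 genes 3 were called higher in taf5-17, 1 lower in taf5-45 and 1 higher in taf5-10.4. With a replicate block it was 7 higher and 1 lower, 4 and 2, and 2 and 0. Adjusted over the list alone 0 were called in taf5-10.4. Among 8 selectable marker genes ADE2 rose by 1.92, 2.27 and 2.35, and URA3 fell in taf5-17 (-1.39) and taf5-45 (-0.87). The list medians were 0.81, 0.86, 0.04 and 0.66, called in taf5-10.4 (adjusted p = 0.0237, and adjusted p = 0.314 with an estimated correlation), where it was 0.33 without its replicate 2.

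In taf5-408 the mitochondrial ribosomal protein genes had a median of 0.65 over 73 genes, against -0.33, -0.11 and 0.18 in taf5-17, taf5-45 and taf5-10.4. The last was 0.32 and -0.03 without wild type replicates 1 and 2 and 0.05 without taf5-10.4 replicate 1. Camera called that list at adjusted p = 1.57e-24 in taf5-408, and adjusted p = 0.296 with an estimated correlation, while limma called 0 of its genes (18 higher at an unadjusted p under 0.05). Of the 15 lists camera called in taf5-408, 0 held with an estimated correlation, and the proteasome was not called with a replicate block (adjusted p = 0.0518). Centring on the mitochondrial ribosomal protein genes shifts all genes of a sample alike and took 9 positive medians below 0, while their differences from the median of all genes, which it cannot change, lay between 0.12 and 0.54. Leaving out 1 sample moved the medians of 12 of the 15 by over 1.5 times. Without taf5-408 replicate 2 the medians were -0.33 for G1/S genes, -0.17 for Hsf1 chaperones, -0.02 for histones and -0.08 for the proteasome, without wild type replicate 1 they were -0.03 for G1/S genes and -0.13 for Hsf1 chaperones, and without wild type replicate 2 -0.07 for stress genes. The other moved medians follow. Without wild type replicate 1 those of stress, G2/M, iron and tricarboxylic acid genes were 1.24, -1.002, 0.10 and 1.05, and TFIID 0.11. Without wild type replicate 2 those of Hsf1, G1/S, G2/M, proteasome, tricarboxylic acid and cell wall genes were 1.16, 0.60, -0.11, 0.18, 0.20 and 0.10. Without taf5-408 replicate 1 those of glycolysis, Hsf1, stress, TFIID, G1/S and G2/M genes were 0.20, 0.78, 0.14, 0.37, 0.78 and -0.27, and of histone, iron, proteasome and cell wall genes 0.76, 0.57, 0.29 and 0.12. Without taf5-408 replicate 2 those of translation factors, stress, TFIID, G2/M, iron and cell wall genes were -0.37, 1.00, 0.00, -0.86, 0.01 and 0.49. The count of lists was 7 without wild type replicate 1 at 37 °C and 9 without taf5-408 replicate 2 at 37 °C. Camera called 22 lists in taf5-17, 16 in taf5-45 and 20 in taf5-10.4, of which 1 in each, the cytosolic ribosomal proteins, held with an estimated correlation. By fry, which tests a list against 0, more lists passed. Among them were translation factors in these alleles (adjusted p = 0.00116, 0.00280 and 0.0276) and tricarboxylic acid genes (0.0270, 0.00831 and 0.0117). Stress genes did not pass fry (0.321, 0.295 and 0.432), nor did ribosome biogenesis genes (0.117, 0.145 and 0.427). With a replicate block ribosome biogenesis genes passed fry in taf5-17 and taf5-45 (adjusted p = 0.0184 and 0.0126) and not in taf5-10.4 (0.161). In taf5-408 the smallest adjusted p by fry was 0.205, for cytosolic ribosomal proteins, which passed with a replicate block (adjusted p = 0.00899). A list's median and its test differed in sign for 2, 4, 5 and 3 of the 33 lists in taf5-17, taf5-45, taf5-408 and taf5-10.4.

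**Figure D3:**
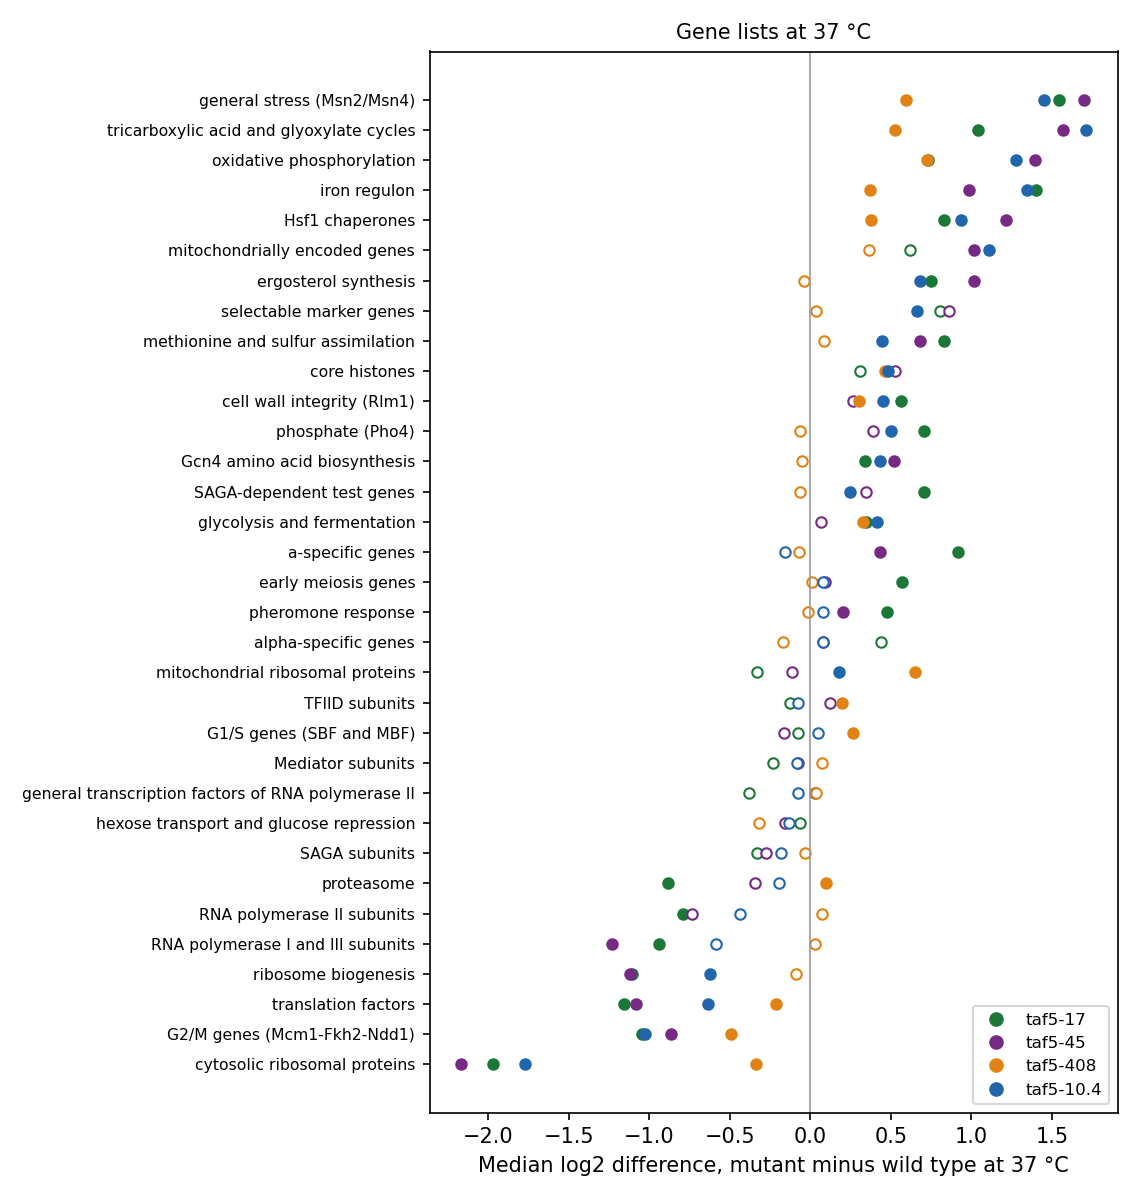
Median log2 difference from wild type at 37 °C of each of the 33 gene lists (rows) in the 4 alleles (colours); filled points passed camera with a preset correlation of 0.01 at an adjusted p under 0.05, open points did not. Cytosolic ribosomal proteins lie at -1.97, -2.17, -0.34 and -1.77, the lowest in each allele except taf5-408. There G2/M genes lie lowest, at -0.49. When samples are centred on mitochondrial ribosomal protein genes, 9 of the 15 filled taf5-408 medians fall below 0, as all genes shift alike.

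TAF5 itself (YBR198C, chromosome II, 616122 to 618518) rose at 37 °C in taf5-17, from 13.09 ± 0.03 (SD, n = 2) in wild type to 14.34 ± 0.30, a difference of 1.25 ± 0.37 (SE, adjusted p = 0.0355), and in taf5-45, by 1.40 (adjusted p = 0.0250). The difference of 1.28 in taf5-10.4 was not called (adjusted p = 0.0553), but was with a replicate block (adjusted p = 0.00184), and that of 1.05 in taf5-408 was not (adjusted p = 0.706). At 23 °C the differences were 0.51, 0.52, 0.80 and 0.64 in taf5-17, taf5-45, taf5-10.4 and taf5-408, none of them called.

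The number of genes changed in the same direction in all 4 alleles at 37 °C depended on how the runs were modelled. A replicate block gave 14, and a block within each temperature more. Without such a block 5 genes were called. They were YHR007C-A (chromosome VIII, 122545 to 122760), GAS2 (YLR343W, chromosome XII, 816094 to 817761), a glucanosyltransferase gene of the spore wall, ULI1 (YFR026C, chromosome VI, 205736 to 206245) and CYC1 (YJR048W, chromosome X, 526250 to 526579), the iso-1-cytochrome c gene, which rose, and BNA1 (YJR025C, chromosome X, 471053 to 471586), of NAD synthesis, which fell. GAS2 rose by 4.19, 4.69, 2.80 and 4.75 in taf5-17, taf5-45, taf5-408 and taf5-10.4 (SE 0.33), ULI1 by 4.12, 3.92, 2.08 and 3.76 (SE 0.30) and CYC1 by 1.87, 1.84, 1.90 and 1.83 (SE 0.29). BNA1 differed by -1.02, -1.36, -1.62 and -2.09 (SE 0.23). In taf5-408 the adjusted p-values of YHR007C-A, GAS2, ULI1, CYC1 and BNA1 were 0.00141, 0.00437, 0.0194, 0.0269 and 0.0194. In taf5-17, taf5-45 and taf5-10.4 together 141 genes rose and 280 fell, 119 of the latter cytosolic ribosomal protein genes. Independent lists of these sizes would share 0.60 and 3.50 genes, and over all 4 alleles 4e-04 and 6e-04. The alleles share the same 2 wild type samples, which correlates their differences: across genes r was 0.57 to 0.93 between alleles and 0.498 in simulated unchanged groups. The covariance was 0.257 to 0.876, against 0.156 simulated and 0.0659 simulated with the spread of the model with a replicate block. In 20 simulations of unchanged groups against shared controls, with as many top genes per allele and direction as were called, the 3 alleles shared a mean of 33.9 higher and 74.3 lower genes and all 4 a mean of 1.55 and 0.65. The highest numbers shared were 42 and 88 in the 3 alleles, and 4 and 1 in all 4, as many as the 4 and 1 measured. This simulation was chosen after the results were seen, and part of the excess over independent lists may come from the shared controls. Simulated unchanged groups called at an adjusted p under 0.05 shared a mean of 0 genes. The 5 genes were 14 with a replicate block, 0 with only the groups of each contrast, 0 after centring on mitochondrial ribosomal protein genes, 1 without wild type replicate 1 at 37 °C, and 3 and 1 without taf5-408 replicates 1 and 2. The 421 genes were 913, 0 and 143 in the first 3 of these settings, 229 without wild type replicate 2 at 37 °C, and 248 and 235 without taf5-10.4 replicates 1 and 2.

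**Figure D4:**
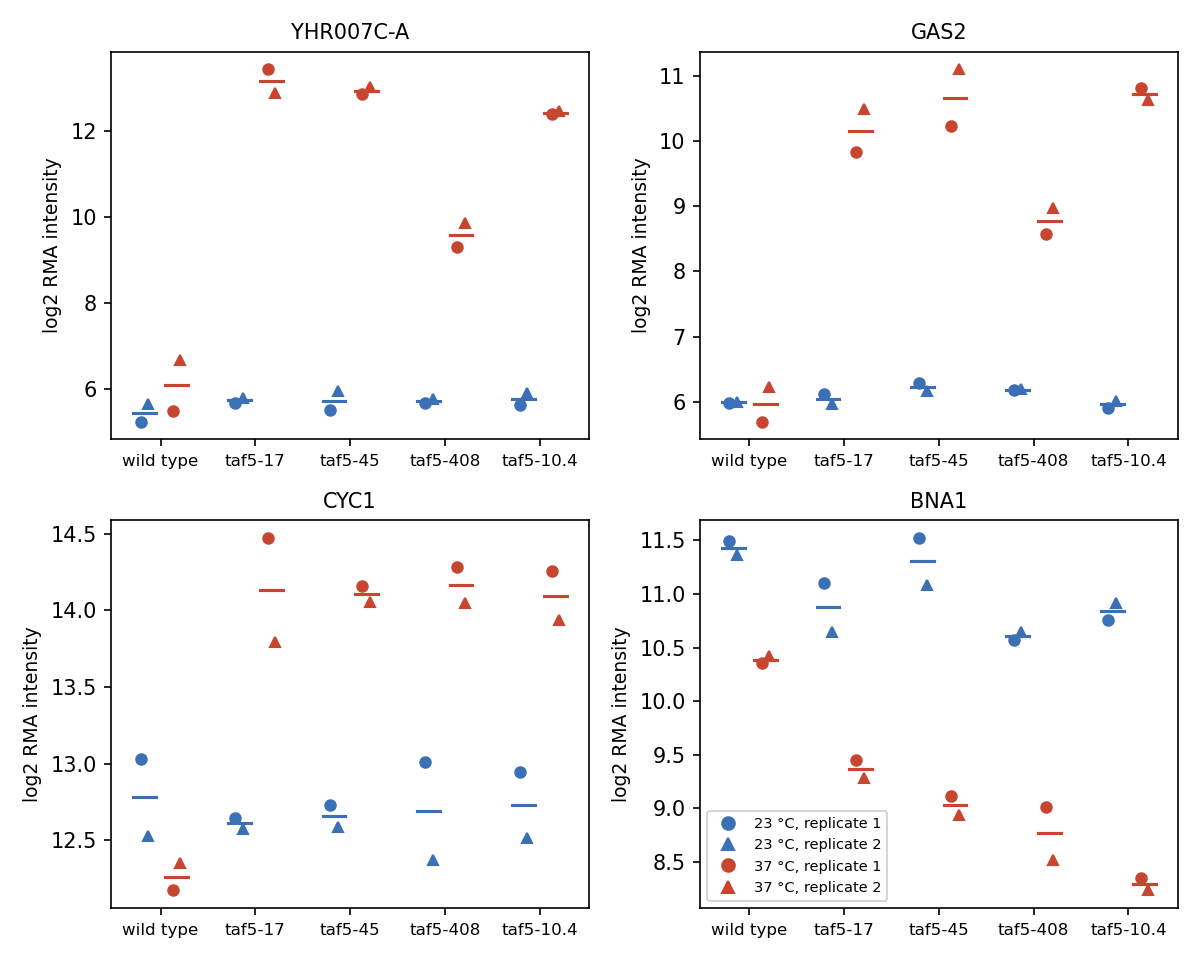
Log2 RMA intensity of YHR007C-A, GAS2, CYC1 and BNA1 in each sample, by genotype; blue is 23 °C, red 37 °C, circles replicate 1, triangles replicate 2 and lines group means. At 37 °C YHR007C-A has a group mean of 6.09 in wild type and 9.59 to 13.17 in the mutants, and BNA1 10.39 in wild type and 8.29 to 9.37 in the mutants.

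The alleles were compared with each other at 37 °C to ask whether they differ. taf5-408 stood apart: its ribosomal protein genes lay above those of the other 3 alleles, while IRC15, YHR007C-A and the short open reading frame YBR182C-A lay below. Against taf5-408, 248 genes were higher and 423 lower in taf5-17, 149 higher and 338 lower in taf5-45, and 36 higher and 130 lower in taf5-10.4. The ribosomal protein medians were -1.64 in taf5-17 minus taf5-408 (110 genes lower), -1.85 in taf5-45 minus taf5-408 (120 lower) and 1.42 in taf5-408 minus taf5-10.4 (103 higher), with the same sign in each scaling (p = 7.66e-04, 1.70e-04 and 6.54e-05 by camera with an estimated correlation). IRC15 was 4.03 ± 0.49 higher in taf5-17 and 3.83 higher in taf5-45 than in taf5-408, and YBR182C-A 3.89 and 3.82. HXT5 was higher (3.93) and PHO3 lower (-3.05) in taf5-45, and RPS6A (-2.34) and RPL38 (-2.31) were lower in taf5-17. Against taf5-10.4, taf5-408 had higher RPS3 (1.94) and RPS6B (1.91) and lower IRC15 (-3.15), YHR007C-A (-2.85) and AGA1 (-2.72).

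Between taf5-17 and taf5-45 limma called 0 genes (480 at an unadjusted p under 0.05, 9 calls with limma-trend). taf5-17 and taf5-10.4 differed in 6 genes, of which 5 were higher, among them YGR109W-A (1.87, overlapping YGR109W-B), YBR182C-A (1.85) and YIR018C-A (1.63), and 1 was lower, TPD3 (-1.57). taf5-45 and taf5-10.4 differed in YGR109W-A (2.08) and YBR182C-A (1.78). Ribosomal protein medians were -0.44 in taf5-45 minus taf5-10.4 (p = 0.00231 by camera with an estimated correlation), 0.31 in taf5-17 minus taf5-45 (p = 0.0648, and 0.0338 with a replicate block) and -0.18 in taf5-17 minus taf5-10.4 (p = 0.325), the last above 0 after cyclic loess and after centring on mitochondrial ribosomal protein genes. With a replicate block the counts were 1543, 1225 and 368 against taf5-408 for taf5-17, taf5-45 and taf5-10.4 and 44 between taf5-17 and taf5-10.4. With only the 2 groups of a contrast limma called 0 in each of the 6 pairs, with 827, 1319 and 798 against taf5-408, 55 for taf5-17 and taf5-45, 110 for taf5-17 and taf5-10.4, and 282 for taf5-45 and taf5-10.4 at an unadjusted p under 0.05. Without taf5-17 replicate 2 at 37 °C, taf5-17 differed from taf5-45, taf5-408 and taf5-10.4 in 648, 1348 and 520 genes, and from taf5-45 in 1 gene without taf5-17 replicate 1 and 4 without taf5-45 replicate 2. Without taf5-408 replicate 1 or 2, the counts were 338 and 243 against taf5-17, 268 and 244 against taf5-45, and 79 and 79 against taf5-10.4. Between taf5-45 and taf5-408 they were 307 and 253 without taf5-45 replicate 1 or 2. Without taf5-10.4 replicate 1 or 2, limma called 0 genes against taf5-17 in both cases, and 83 and 90 against taf5-408. Between taf5-45 and taf5-10.4 it called 0 without any of the 4 samples.

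At 23 °C the mutants were compared with wild type to ask what the alleles do at the permissive temperature. No gene was called in any allele by limma, with 15, 3, 33 and 10 genes at an unadjusted p under 0.05 in taf5-17, taf5-45, taf5-408 and taf5-10.4. Unchanged groups would give more genes than that at this p, so the test was conservative. The model without a replicate block counts the difference between runs as spread. Its median SE was 0.398, against an SD over all genes of 0.20 to 0.26 for these differences. With a replicate block the median SE was 0.288, and limma called 0 genes in each allele. Among the lists camera called, methionine and sulfur genes had medians of -0.56 in taf5-17, -0.58 in taf5-45 and -0.34 in taf5-408, selectable marker genes -0.45 in taf5-17 and Gcn4 targets -0.41 in taf5-17. Camera called 6, 11, 15 and 5 lists, for methionine and sulfur genes at adjusted p = 2.75e-12 and 4.10e-19 in the first 2, but 0 held with an estimated correlation or with fry (adjusted p = 0.321 and 0.193 with an estimated correlation). On simulated data with changes in taf5-17 at 23 °C the model called 14 of 100 genes changed 2-fold and 72 of 100 changed 4-fold. The simulated arrays varied independently. In the measured groups at 23 °C the difference between runs was shared, at r of 0.861 or more between groups. These shares therefore need not hold for the measured contrast, and 0 calls do not show that no gene changed.

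The interaction asks what the shift to 37 °C adds to a mutant's difference, free of dye. Of the genes called, 699 of 717 in taf5-17, 499 of 501 in taf5-45, 277 of 278 in taf5-10.4 and 2 of 2 in taf5-408 were also called in the same direction against wild type at 37 °C, a comparison with the same 37 °C samples. YHR007C-A rose more with the shift than in wild type, by 6.79 ± 0.40 in taf5-17, 6.57 in taf5-45 and 6.02 in taf5-10.4, GAS2 by 4.46 in taf5-45 and 4.78 in taf5-10.4, DAL80 by 4.65 in taf5-45 and YOR072W-B by 5.18 in taf5-17 and 4.15 in taf5-10.4. Ribosomal protein genes fell more than in wild type, 117 of 132 in taf5-17, 121 in taf5-45 and 112 in taf5-10.4 (120, 129 and 126 adjusted over the list alone), at medians of -2.03, -2.25 and -1.80 with the same sign in each scaling. RPL43B had interactions of -2.95, -3.10 and -2.61, RPS6B of -2.92 in taf5-17 and -2.61 in taf5-10.4, RPS3 of -3.27 in taf5-45, PHO3 of -3.29 in taf5-17 and -3.35 in taf5-45 and SPO12 of -2.59 in taf5-10.4. The list's calls held with an estimated correlation in these alleles (adjusted p = 0.0162, 0.00384 and 0.00339) and not in taf5-408, where the median was -0.30 (adjusted p = 0.203 with an estimated correlation) and limma called 0 of its genes (9 lower at an unadjusted p under 0.05). Methionine and sulfur genes had interaction medians of 1.42, 1.38 and 0.50 in taf5-17, taf5-45 and taf5-10.4 (smallest adjusted p = 0.369 with an estimated correlation), against 0.42 in taf5-408 (-0.02 after centring on mitochondrial ribosomal protein genes, which moved the median of all genes to -0.45).

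In the interaction 271 genes were higher and 446 lower in taf5-17, 169 and 332 in taf5-45, 94 and 184 in taf5-10.4, and 2 higher in taf5-408, YHR007C-A (3.23, adjusted p = 0.0148) and GAS2 (2.61, adjusted p = 0.0375), both at adjusted p = 0.0578 with a replicate block. Without the array block the counts were 364, 306 and 166 for taf5-17, taf5-45 and taf5-10.4, with only the groups of the contrast 180 for taf5-17, and after centring on mitochondrial ribosomal protein genes 430, 295 and 129. For taf5-17 the count was 366 and 362 without wild type replicate 1 or 2 at 23 °C, 469 and 386 without those at 37 °C, and 1341 without its own replicate 2 at 37 °C. For taf5-45 the counts were 307, 263 and 298 without wild type replicate 1 or 2 at 23 °C or replicate 2 at 37 °C, 319 and 310 without its own 23 °C replicates 1 and 2, and 314 without its replicate 2 at 37 °C. For taf5-10.4 the same 3 wild type omissions gave 166, 155 and 180, and its own replicate 2 at 23 °C 159. The taf5-408 count was 0 or 1 without any of the 8 samples of its contrast. Camera called 23, 18, 15 and 18 lists in taf5-17, taf5-45, taf5-408 and taf5-10.4, of which 1, 1, 0 and 1 held with an estimated correlation. The number of lists was 15 in taf5-17 and 9 in taf5-408 without their own replicate 1 at 37 °C, and 10 in taf5-10.4 without its replicate 2 at 23 °C.

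The shift from 23 °C to 37 °C within wild type shows the response against which the mutants are set, with dye and temperature inseparable. The acid phosphatase gene PHO12 (-5.94 ± 0.46) and its near-identical paralog PHO11 (-5.89) fell most. The acid phosphatase gene PHO5 also fell (-2.38, adjusted p = 0.0912 with a replicate block). The a-factor genes MFA1 (-2.46) and MFA2 (-1.23, adjusted p = 0.0786 with a replicate block) and BAR1 (-1.70), which encodes the alpha-factor protease, fell, as did TDH2 (-1.69), SPL2 (-1.59), GPP1 (-1.51) and GPM3 (-1.32). The largest rise was that of GSC2, a glucan synthase subunit gene, by 3.28 ± 0.66, and PST1, a cell wall protein gene, rose by 2.44, as did KDX1 (1.66), MOH1 (2.91), YGP1 (2.57), YNL277W-A (2.30, adjusted p = 0.0571 with a replicate block), CPR6 (1.92), KTR2 (1.91), GCG1 (1.84) and HPA3 (1.67). Of 16 phosphate genes 4 fell (10 adjusted over the list alone) at a median of -0.98, of 7 a-specific genes 3 (4 adjusted over the list alone) at -1.21, and of 132 ribosomal protein genes 10 (67 adjusted over the list alone, 5 with a replicate block) at -0.47. Of cell wall integrity genes 3 of 22 rose (6 adjusted over the list alone) at 0.76. Camera called 13 lists, and none held with an estimated correlation, except ribosomal protein genes with a replicate block (adjusted p = 0.0480). Without that block the phosphate list had adjusted p = 0.102, a-specific and ribosomal protein genes adjusted p = 0.0502 each and cell wall integrity genes adjusted p = 0.214 with an estimated correlation.

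In wild type 34 genes rose and 32 fell with the shift, 66 in all, against 2052 in taf5-17, 1815 in taf5-45, 1363 in taf5-10.4 and 297 in taf5-408. The wild type count was 15 without the array block, 9 after centring on mitochondrial ribosomal protein genes, and 9, 7, 9 and 18 without wild type replicate 1 or 2 at 23 °C or replicate 1 or 2 at 37 °C. With only the groups of the contrast limma called 0 in wild type (1031 at an unadjusted p under 0.05), 0 in taf5-408 (884), 835 in taf5-17 and 407 in taf5-10.4. Single samples took taf5-45 to 933 without its replicate 2 at 23 °C and to 1193 and 1044 without its 37 °C replicates 1 and 2, and taf5-10.4 to 583, 796 and 672 without the same samples of its own. For taf5-408 the count was 145 and 31 without its 23 °C replicates 1 and 2, 98 and 37 without its 37 °C replicates 1 and 2. Without the array block the counts were 140 in taf5-408 and 871 in taf5-10.4.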

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

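Of the tests of an explanation below, those on the matched gene lists and on the 2 blocks of probe sets were chosen before their result was seen, and the tests against taf5-408, on stress genes, on TAF5, on cross-run correlations and on dim genes only after.

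The response to the temperature shift differed between a mutant and wild type, by limma's interaction term, in 717 genes in taf5-17, 501 in taf5-45, 278 in taf5-10.4 and 2 in taf5-408. The alleles also differed from each other at 37 °C: taf5-17 from taf5-408 in 671 genes and from taf5-10.4 in 6, taf5-45 from taf5-408 in 487 and from taf5-10.4 in 2, and taf5-408 from taf5-10.4 in 166. With groups of 2 samples, regrouping the samples can give no test, and no sample can be tested as an outlier of its group.

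The first pattern is the fall of cytosolic ribosomal protein genes at 37 °C in taf5-17, taf5-45 and taf5-10.4. As these genes are bright, saturation or an intensity-dependent normalization was tested with 10000 random lists matched on mean intensity. Of these, 0 percent had a median as low in any of the 3 alleles (matched medians 0.04 to 0.68). That argues against it as the cause of the fall. The middle matched median was 0.26, 0.39 and 0.46 in taf5-17, taf5-45 and taf5-10.4, against -0.10, -0.09 and -0.08 over all genes. Bright genes outside the list thus lay above the rest, and whether this raised other bright lists was not tested. Unusual wild type samples are argued against by the medians against taf5-408, a comparison without wild type, of which the one closest to 0 was -1.42 in taf5-10.4. A general stress or slow-growth response stays open: in the interaction with temperature, ribosome biogenesis genes were lower and stress genes higher in 5 of 6 pairs of allele and run, the exception being taf5-10.4 in run 1, where ribosome biogenesis stood at 0.09 and ribosomal proteins at -1.77. Against wild type at 37 °C all 6 pairs had both directions, taf5-10.4 in run 1 at -0.22 and 0.27. The allele itself, which the design names, also stays open, untested.

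The second pattern is the low number of genes changed in taf5-408 at 37 °C. It was 5, against 1047, 857 and 484 in taf5-17, taf5-45 and taf5-10.4, in a model that counts the difference between runs as spread. With a replicate block it was 16 against 2017, 1767 and 1122, and a block within each temperature called more in each allele. The number was low beside the other alleles in each of these models, but its size depended on the model. A wild type culture carrying the taf5-408 label is argued against by TAF5 itself, which lay 2.81 standard errors above wild type in taf5-408 (4.70 with a replicate block), at 1.21 and 0.89 in the 2 same-numbered pairs. A weaker form of the response of the other alleles is a candidate explanation: the taf5-408 difference of 1 run correlated across genes with the mean difference of the other 3 alleles of the other run at r = 0.330 and 0.345, with slopes of 0.236 and 0.146. The same measure in taf5-10.4, against taf5-17 and taf5-45, gave 0.691 and 0.649. Not every difference was weaker in taf5-408. Those of YHR007C-A, GAS2 and ULI1 were, but CYC1 rose about as much and BNA1 fell more than in taf5-17 and taf5-45. The median of mitochondrial ribosomal protein genes was 0.65 in taf5-408, against -0.33, -0.11 and 0.18 in taf5-17, taf5-45 and taf5-10.4. Genes are not independent replicates, and scan number differs between taf5-408 and wild type.

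The third pattern is the taf5-17 replicate 1 sample at 37 °C, whose 2 blocks of probe sets differed most. Its deviation from replicate 2, relative to the other alleles, correlated between block 1 and block 2 at 0.859 across genes. That argues against random spot noise as the whole of this deviation. It cannot exclude added spot noise, since a deviation common to both blocks says nothing about the larger difference between them. Raised background that lifts dim genes is a candidate explanation: the median difference from wild type of the dimmest 1434 genes was 0.34 in replicate 1 and 0.08 in replicate 2, against 0.04 and 0.04 in taf5-45. Early meiosis genes stood at 0.78 and 0.34 in replicates 1 and 2 and a-specific genes at 0.98 and 0.16, while ribosomal protein genes were alike, at -1.87 and -1.91. No biological explanation was tested for this sample.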

How the results depend on the processing

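A replicate block within each temperature, scan number as a block, each block of probe sets alone and omission of the taf5-17 replicate 1 array were chosen only after the results were seen. No single named gene that passed the threshold changed sign, but medians of called lists changed sign under a scaling: after centring 9 of 15 in taf5-408 at 37 °C and 10 of 15 in its interaction, through the shift of all genes, and after cyclic loess 2 of 10 between taf5-17 and taf5-10.4, 1 of 9 between taf5-17 and taf5-45 and 1 of 12 between taf5-45 and taf5-10.4. Centring also turned 2 of 6, 2 of 11 and 3 of 15 at 23 °C in taf5-17, taf5-45 and taf5-408, 1 of 23 in the taf5-17 interaction, and 1 of 16 and 3 of 16 in the shifts of taf5-17 and taf5-408. Between alleles it turned 3 of 18 for taf5-17 and taf5-408, 3 of 10 for taf5-17 and taf5-10.4, 1 of 19 for taf5-45 and taf5-408, 2 of 12 for taf5-45 and taf5-10.4 and 1 of 23 for taf5-408 and taf5-10.4. With samples left out apart, of the values that answer a comparison 435 stayed within 1.5 times their count or within their spread and 91 moved. Of the values of single named genes, 14895 kept their side of the threshold, 463 passed it newly and 617 lost it. With 1 sample left out, 112 of the values that answer a comparison stayed and 80 moved, and of single named genes 5944 stayed, 78 passed newly and 550 lost the threshold. The counts stayed within 1.5 times under quantile normalization, the median of a gene's 2 values and a fold minimum of 1.5. Except where the fit has fewer genes or samples, the cause was not tested.

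Centring on mitochondrial ribosomal protein genes gave 389, 372, 0 and 184 genes at 37 °C in taf5-17, taf5-45, taf5-408 and taf5-10.4, and interactions of 430, 295, 0 and 129. It gave 9 in the wild type shift, 1044 between taf5-17 and taf5-408, 0 between taf5-17 and taf5-10.4 and between taf5-45 and taf5-10.4, and 8 between taf5-408 and taf5-10.4. Genes changed in all 4 alleles fell to 0 and those in taf5-17, taf5-45 and taf5-10.4 to 143. After cyclic loess taf5-17 and taf5-10.4 differed in 1 gene. Without the dimmest 25% of genes taf5-17 and taf5-45 each differed from taf5-10.4 in 0.

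Without the array block the interactions were 364, 306, 0 and 166 in taf5-17, taf5-45, taf5-408 and taf5-10.4, and the shifts 15 in wild type, 140 in taf5-408 and 871 in taf5-10.4. With a replicate block the counts at 37 °C were 2017, 1767, 16 and 1122, and the taf5-408 interaction 0. Allele pairs were 1543 for taf5-17 and taf5-408, 44 for taf5-17 and taf5-10.4, 1225 for taf5-45 and taf5-408, and 368 for taf5-408 and taf5-10.4, with 14 genes in all 4 alleles and 913 in the other 3. With limma-trend the taf5-408 interaction was 1, and taf5-17 differed from taf5-45 in 9 and from taf5-10.4 in 24.

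With only the groups of the contrast limma called 0 in each allele against wild type at 37 °C, 0 in the 5 allele pairs that had calls, 0 genes in all 4 alleles and 0 in the other 3. The interactions were 180 in taf5-17 and 0 in taf5-408, and the shifts 0 in wild type, 835 in taf5-17, 0 in taf5-408 and 407 in taf5-10.4. With groups of 2, such fits have few residual degrees of freedom. With only arrays of scan 1 taf5-17 and taf5-408 differed in 40 genes and taf5-45 and taf5-408 in 0.

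With a replicate block within each temperature the counts at 37 °C were 2545, 2334, 108 and 1615, the interactions 1705, 1278, 4 and 750, and the shifts 520 in wild type and 800 in taf5-408. Allele pairs were 29 for taf5-17 and taf5-45, 2200 for taf5-17 and taf5-408, 183 for taf5-17 and taf5-10.4, 1887 for taf5-45 and taf5-408, and 720 for taf5-408 and taf5-10.4, with 92 genes in all 4 alleles and 1318 in the other 3. With block 1 of the probe sets alone taf5-408 had 3 genes at 37 °C and an interaction of 1, taf5-17 and taf5-45 each differed from taf5-10.4 in 0, and 3 genes changed in all 4 alleles. With block 2 alone taf5-17 differed from taf5-45 in 1 gene and from taf5-10.4 in 3, and taf5-45 from taf5-10.4 in 1. Without the taf5-17 replicate 1 array taf5-17 had 668 genes at 37 °C and 14 interaction lists, interactions were 779 in taf5-45 and 438 in taf5-10.4, shifts 175 in wild type and 508 in taf5-408, and taf5-17 differed from taf5-408 in 308 and from taf5-10.4 in 0.

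Leaving out 1 sample at a time, with the lone sample of a group assumed to vary like the other groups, gave 580 to 1397 genes at 37 °C in taf5-17, 443 to 679 in taf5-45, 1 to 5 in taf5-408 and 246 to 338 in taf5-10.4. It gave 17 to 22, 15 to 18, 7 to 11 and 15 to 20 lists, and ribosomal protein medians of -1.98 to -1.86, -2.35 to -2.07, -0.39 to -0.33 and -1.81 to -1.68. Genes in all 4 alleles numbered 1 to 6 and in the other 3 229 to 496. Interactions ran from 362 to 1341, 263 to 403, 0 to 1 and 155 to 201 genes, and 15 to 23, 15 to 20, 9 to 15 and 10 to 22 lists. Shifts ran from 7 to 18 in wild type, 1607 to 2122 in taf5-17, 933 to 1373 in taf5-45, 31 to 145 in taf5-408 and 583 to 1063 in taf5-10.4. Allele pairs ran from 0 to 648 (taf5-17 and taf5-45), 243 to 1348 (taf5-17 and taf5-408), 0 to 520 (taf5-17 and taf5-10.4), 244 to 307 (taf5-45 and taf5-408) and 79 to 90 (taf5-408 and taf5-10.4), with 0 for taf5-45 and taf5-10.4. At 23 °C limma called 0 genes in each allele throughout. No detection calls come with the arrays, so signal over background was not measured for single genes.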

Other observations

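The comparison of the 2 runs was chosen only after the results were seen. Run 2 minus run 1 over the 5 genotypes gave 1542 genes higher and 1258 lower at 23 °C, and 1220 higher and 1042 lower at 37 °C. At 23 °C the general stress genes under Msn2 and Msn4 were lower in run 2 by a median of -3.16, 36 of 37 of them called (adjusted p = 7.72e-24, and adjusted p = 0.415 with an estimated correlation), among them the glycogen genes GPH1 (-5.58), GSY1 (-5.51) and GLC3 (-5.41). Outside that list RGI1 (-7.33), TMA10 (-6.82) and HSP30 (-6.61) were lower. These genes were chosen after their values were seen. Ribosome biogenesis genes were higher by 0.92, 68 of 90 called (adjusted p = 0.509 with an estimated correlation), G1/S genes by 0.81, 33 of 41 called (adjusted p = 0.445 with an estimated correlation), and iron regulon genes by 1.16, 15 of 22 called, with SIT1 at 4.51 and FTR1 at 3.47 (adjusted p = 0.445 with an estimated correlation). At 37 °C the Hsf1 chaperone genes were higher in run 2 by 0.94, 23 of 27 called (adjusted p = 0.495 with an estimated correlation), and hexose transport and glucose repression genes lower by a median of -1.59, 15 of 22 called lower and 2 higher (adjusted p = 0.402 with an estimated correlation).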
